A study of Rattus norvegicus with 6 samples.

How the data were processed

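RNA was measured by sequencing in the paraventricular nucleus of the hypothalamus of male Holtzman rats, a laboratory stock. There were 2 groups, control and furosemide, with 3 libraries in each, and each library was made from tissue of 3 rats pooled together. Per the labels' protocols, RNA was taken up in QIAzol, purified on RNeasy columns and made into libraries with a TruSeq mRNA kit. Such a kit selects polyadenylated RNA, so transcripts without a poly(A) tail are measured poorly. Whether the kit version or the counting kept the strand is not given in the sources used here.

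The deposited table holds raw read counts per gene, as whole numbers, for 32402 rat Ensembl gene identifiers in 6 columns. FastQC, TopHat, HTSeq and edgeR are named per the submitters' processing notes, without versions or parameters. The genome build and annotation release are not given in the sources used here, so no coordinates are reported. The columns were assigned to libraries by the group and replicate number in their names. No row of the table collects unassigned reads.

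The table lists genes by identifier alone. None of the 32402 identifiers (0) could be matched to a symbol, because the reference gene table used here, which has 47357 rows, lists no Ensembl identifiers. The 21 pathway lists and 17 marker lists of cell types and neighbouring regions, all fixed by symbol, could therefore not be tested. The same holds for the genes to be named by symbol whatever their result, and for members of the lists to be named as examples.

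Counts were analysed in R 4.3.3. Genes were kept by the default filterByExpr setting of edgeR 4.0.16, which left 16344 genes holding 99.9% of all counts. Library sizes were scaled by TMM factors, which lay between 0.994 and 1.01. Furosemide was compared with control by the edgeR quasi-likelihood F test (glmQLFit and glmQLFTest) with treatment group as the only term, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The standard error of each log2 fold change was taken as its size divided by the square root of the F statistic, and 95% confidence intervals used the moderated degrees of freedom. Expression is given as CPM, counts scaled to a common TMM-adjusted library size, computed here from the deposited counts.

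The gene lists, the test, the rule for single genes and the following alternatives were fixed before the data were examined, except where stated. The rule took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 1 CPM and no overlap between groups. With fewer than 5 past the threshold, as here, it took the 12 genes with the smallest unadjusted p and that CPM minimum, described as not having passed. For lack of symbols only the 2 with the smallest p in each direction are named, a limit applied after the data were examined. The alternatives were RLE size factors, upper-quartile factors or library size alone, no low-count filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, the edgeR exact test, limma-voom (limma 3.58.1) with sample quality weights, robust dispersions, a replicate block, 1 surrogate variable from sva 3.50.0, a test against a fold change of 1.2, and leaving out each library. Added after seeing the data were the non-legacy form of the quasi-likelihood fit, thinning every library to the smallest total, and removal of a set of genes raised in 1 library.

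The fit was tested on 10 simulated data sets, each with counts drawn for the 16344 tested genes from the libraries' own means, sizes and dispersions and with 200 genes changed by 1 of 3 fold sizes. At an adjusted p under 0.05 the quasi-likelihood test recovered 39.6% of genes changed 1.2-fold, 80.1% of those changed 1.5-fold and 91.4% of those changed 2-fold. With no gene changed, it made a mean of 1.4 calls, the exact test 5.2 and DESeq2 0.2. The simulation used dispersions already shrunk towards the trend, so these shares hold for genes with dispersions of that kind. They also hold only where about 200 genes change. With fewer changed genes the adjusted threshold is harder to pass, and the shares would be lower. Genes were drawn independently of one another, so the numbers of false calls leave out variation that many genes share within a library. Splits of the real libraries that mixed the groups gave up to 41 calls in the exact test and up to 9 in DESeq2. The simulated false calls are therefore not a measure of how many of the real calls are false.

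No 2 libraries were copies of each other. For genes with 10 or more counts in a pair, the median squared difference between libraries of 1 group was 1.69 to 2.05 times the sampling noise over 6 pairs. It was 1.88 to 2.35 times over the 9 pairs that joined the groups. The 9 rats of a group were divided among its 3 pools, per the labels. Dates or batches of dissection, library preparation and sequencing are not given in the sources used here. The p-values therefore describe the spread between these pools, which includes technical variation and averages over the rats within a pool.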

Results

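Gene expression was measured in the paraventricular nucleus of the hypothalamus, the nucleus whose neurons make vasopressin, oxytocin and corticotropin-releasing hormone. The question was how its transcripts stood 24 h after acute sodium loss. Male rats received furosemide, a loop diuretic that makes the kidney excrete sodium, at 10 mg/kg, and then had sodium-poor food and distilled water to drink. What the control rats were injected with and fed is not given in the labels. Tissue from 9 rats per group gave 3 libraries per group, each a pool of 3 rats.

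The control libraries held 21443039, 21669388 and 20911950 counts, and the furosemide libraries 22495415, 21950410 and 22247782. The mean total was 21341459 ± 388802 in controls and 22231202 ± 272881 after furosemide (SD, n = 3 each). All 3 furosemide totals lay above all 3 control totals, and the two-sided exact permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. Between 20202 and 20366 genes had at least 1 count in each library, and the 10 most abundant genes took 5.58% to 6.40% of the counts. Replicate pools were close to one another. The median biological coefficient of variation over the 16344 genes tested was 5.19%, and 85.7% of genes lay under 10%. On log2 CPM, Pearson correlations across genes were 0.9941 to 0.9951 within groups and 0.9939 to 0.9947 between groups (genes are not independent replicates). The first principal component held 22.9% of the variance and the fifth 16.7%, so no single axis dominated the differences between libraries.

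No gene differed between furosemide and control libraries at an adjusted p under 0.05 in the edgeR quasi-likelihood test, with 0 genes higher and 0 lower among the 16344 tested. The smallest adjusted p was 0.0768, shared by 2 genes. At an unadjusted p under 0.05 there were 1322 genes, 624 higher and 698 lower after furosemide, against 817 that would be passed by chance if no gene had changed. On the same 16344 genes the edgeR exact test called 45 (15 higher, 30 lower). DESeq2 called 40 (18 higher, 22 lower), all of them among the same 16344 genes. It started from all 22994 genes with a count and gave 12213 of them no adjusted p, so both tool and gene set differed. The exact test and DESeq2 shared 32 calls. The limma-voom test called 0 genes, with 1375 at an unadjusted p under 0.05. DESeq2 had 689 of its 22994 genes (3.00%) at that level, no more than chance would give. The median absolute log2 fold change was 0.24 among the DESeq2 calls (maximum 0.74) and 0.30 among the calls of the exact test (maximum 3.71). The calls depended on single libraries. The quasi-likelihood test called 6 genes higher and 11 lower without control 1, 1 lower without control 3, and 0 without any other library. The exact test called 113, 33 and 41 genes without control 1, 2 and 3, and 28, 16 and 33 without furosemide 1, 2 and 3. DESeq2 called 33, 14 and 4 without control 1, 2 and 3, and 12, 1 and 19 without furosemide 1, 2 and 3.

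For most genes the data set a narrow bound on any change in the average over the pooled tissue. Changes confined to some of its cells are not bounded in this way. The 95% confidence interval of the fold change lay wholly within 1.5-fold in either direction for 13902 of the 16344 genes (85.1%). Among the 10656 genes with a mean of 10 CPM or more, 10616 (99.6%) were bounded in this way. Among the 1153 genes under 1 CPM only 2 were, so changes larger than 1.5-fold were not excluded at this depth for weakly expressed genes. The median absolute log2 fold change over all tested genes was 0.06. Of 15191 genes with a mean of at least 1 CPM, 83 had an estimated change of 1.5-fold or more, 31 upward and 52 downward, and 71 of them had an unadjusted p under 0.05. The downward genes include many of a set of 20 that stood highest in the control 2 library, described below. The median log2 fold change of that set was -0.99, so the excess of downward genes rests partly on 1 library.

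**Figure D1:**
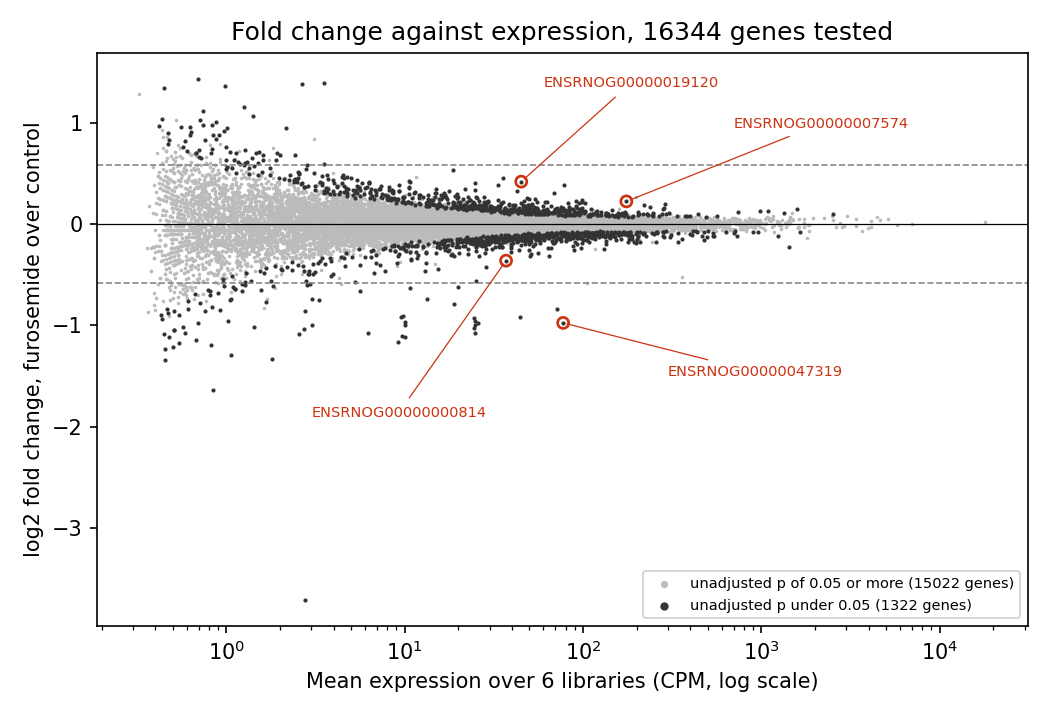
Each point is 1 of the 16344 genes tested, placed by its mean expression over the 6 libraries (CPM, log axis) and its log2 fold change, furosemide over control; dashed lines mark a 1.5-fold change in either direction and circles the 4 genes named in the text. Changes narrow towards 0 as expression rises, and 13902 genes have confidence intervals that stay within the dashed lines.

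None of the genes with the smallest p passed the threshold in the quasi-likelihood test. Of the 12 with the smallest p, 5 were higher and 7 lower after furosemide. For all 12 the 3 control values did not overlap the 3 furosemide values, which the choice by smallest p makes likely. ENSRNOG00000019120 stood at 38.6 ± 2.78 CPM in controls and 51.6 ± 3.46 CPM after furosemide (SD, n = 3 each). Its log2 fold change was 0.42 with a standard error of 0.06, a 1.34-fold difference with an edgeR adjusted p of 0.0768. ENSRNOG00000007574 was at 162 ± 7.21 CPM in controls and 189 ± 1.45 CPM after furosemide, a log2 fold change of 0.22 with a standard error of 0.04 (edgeR adjusted p = 0.124).

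In the opposite direction, ENSRNOG00000000814 was at 41.7 ± 2.23 CPM in controls and 32.4 ± 0.545 CPM after furosemide (SD, n = 3 each). Its log2 fold change was -0.36 with a standard error of 0.05 (edgeR adjusted p = 0.0768). ENSRNOG00000047319 showed the largest difference of the 4 named genes, at 103 ± 29.7 CPM in controls and 52.2 ± 9.00 CPM after furosemide. Its log2 fold change was -0.98 with a 95% interval of -1.31 to -0.64 (edgeR adjusted p = 0.124). The control values of this gene ran from 80.9 to 137 CPM, a wider spread than the 42.0 to 59.3 CPM of the furosemide libraries. The counts behind these 4 genes were between 713 and 4270 per library. Each kept its direction in all 21 alternative analyses, which was nearly certain for genes chosen from these counts whose groups did not overlap. All 4 passed the threshold in the edgeR exact test and in the quasi-likelihood test without a low-count filter or without control 1. In DESeq2 ENSRNOG00000047319 did not (adjusted p = 0.0971) while the other 3 did. Leaving aside the test against a 1.2-fold change, the adjusted p of ENSRNOG00000019120 ran from 5.98e-06 in the exact test to 0.195 without furosemide 1. That of ENSRNOG00000047319 ran from 5.98e-06 in the exact test to 0.515 with robust dispersions. The identifiers were not paired with gene symbols in the sources used here.

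**Figure D2:**
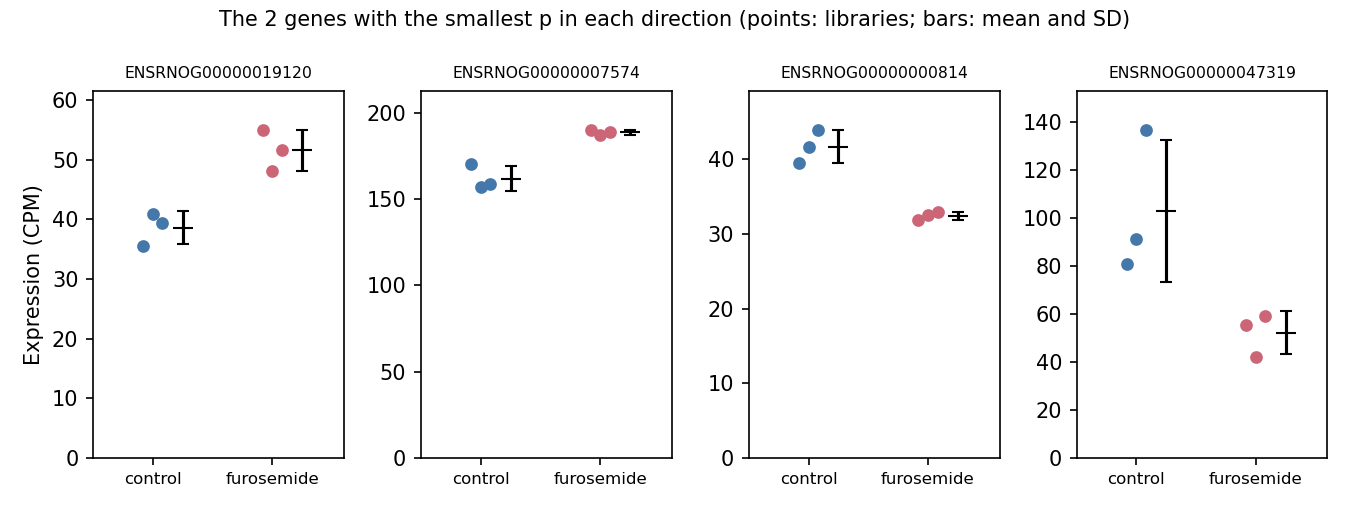
Expression in CPM, on linear axes from 0, of the 2 genes with the smallest p among those higher after furosemide (left) and the 2 among those lower (right); points are single libraries (3 per group) and bars show the mean and SD. The control and furosemide points do not overlap in any panel, which the choice by smallest p makes likely. ENSRNOG00000047319 has the widest control spread, 80.9 to 137 CPM.

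The control and furosemide values did not overlap for 2208 of the 16344 genes (13.5%), of which 1094 were higher and 1114 lower after furosemide. Chance alone gives 10% with 3 libraries against 3. A further 36 genes had counts in all 3 furosemide libraries and in no control library, and 38 showed the opposite, with no more than 6 counts in any library. The largest estimated change among genes of at least 1 CPM was a log2 fold change of -3.71, with a standard error of 0.87. That gene, singled out after its values were seen, had 209 and 117 counts in the control 1 and control 2 libraries, 6 in control 3, and 3, 3 and 20 in the furosemide libraries. Its groups overlapped, and its adjusted p was 0.265 in the edgeR quasi-likelihood test, although it was among the 45 calls of the exact test.

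One control library stood apart for a small set of genes. In the control 2 library, 20 genes were at least 2-fold above each of the other 5 libraries, while no other library had more than 1 such gene. These 20 genes were a median of 3.67-fold above the median of the other libraries, and held 0.108% of the counts in control 2 against 0.03% to 0.034% elsewhere. In the comparison of the groups their log2 fold changes ran from -1.33 to -0.58, and 18 of the 20 had an unadjusted p under 0.05. Without control 2, the library whose excess they were chosen for, that number was 1. Of their 190 pairs, 27 had mean levels within 0.1 of each other on the log2 scale. None of the 20 was among the genes called by DESeq2 or the exact test.

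**Figure D3:**
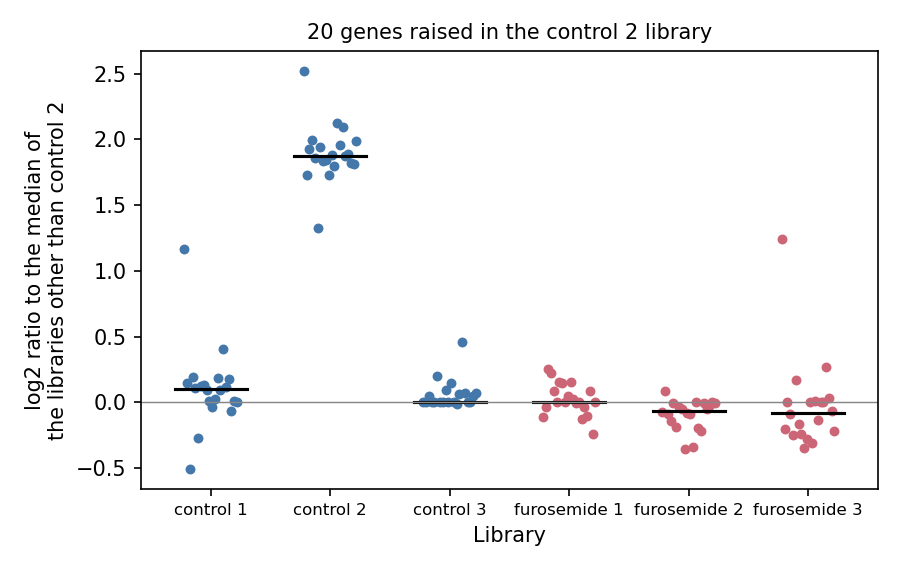
Log2 ratio of each of 20 genes (points) to its median over the 5 libraries other than control 2, shown per library, with black lines at the library medians; controls are blue and furosemide libraries red. The control 2 points centre on 1.88, and the medians of the other libraries lie near 0. For 1 gene the ratio was also 1.17 in control 1 and 1.24 in furosemide 3.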

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

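The non-legacy fit, the thinned libraries and the removal of the 20 genes raised in control 2 were chosen after seeing the data. The count of 0 genes past the adjusted threshold held under RLE, upper-quartile and library-size scaling, the 1 CPM filter, limma-voom, the 1.2-fold test, those added settings and the omission of control 2 or of any 1 furosemide library. It did not hold in the others. Without a low-count filter the quasi-likelihood test called 12 genes higher and 16 lower. DESeq2 called 18 and 22, the exact test 15 and 30, robust dispersions 3 and 1, and 1 surrogate variable 3 and 5. The DESeq2 fit differed from the filtered quasi-likelihood test in its gene set as well as its model, though all its calls were among the filtered genes. For each of these the cause was not tested. The fits without filter, by DESeq2 and by the exact test shared 24 genes. Leaving out 1 library gave 0 to 6 genes higher and 0 to 11 lower, the top values without control 1. Leaving out 1 library moved the 45 calls of the exact test to between 16 (without furosemide 2) and 113 (without control 1), with 28 without furosemide 1. The 40 DESeq2 calls fell to 33, 14 and 4 without control 1, 2 and 3 and to 12, 1 and 19 without furosemide 1, 2 and 3. The count at an unadjusted p under 0.05 ran from 1082 (without control 2) to 1568 (no filter), except 689 in DESeq2 and leaving aside the 1.2-fold test, whose p has another null. Fold changes bounded within 1.5-fold numbered 13137 to 14041. The 4 named genes passed the threshold in 5 or 6 of the 21 alternatives. They kept their direction in all 21, which was nearly certain for genes whose groups did not overlap. With a replicate block 0 genes were higher and 1 lower, ENSRNOG00000047319, but libraries of equal number did not deviate together (correlations of -0.02, -0.01 and -0.09), and no library correlated best with the one of its own number, so the numbers are not read as pairs. The tests of the gene lists and all their alternatives were not run, for lack of symbols. Depth limited genes under 1 CPM, where 2 of 1153 were bounded.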

Other observations

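All tests in this part were chosen after the results were seen, except the count of splits for the quasi-likelihood calls. The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share of splits under 0.05. The real split gave 0 quasi-likelihood calls at an adjusted p under 0.05 and the highest other split 1, so all 10 splits gave as many, which a count of 0 makes certain whatever the data. The exact test called 45 genes in the real split and 41 in the highest other, which set control 1, control 2 and furosemide 3 against the rest, so 1 split was as large, the real one. DESeq2 called 40 genes in the real split and 9 in the highest other, again with 1 split as large. Genes whose groups did not overlap numbered 2208 in the real split and 1258 to 1926 in the others. Genes with an estimated change of 1.5-fold or more numbered 83 in the real split and 47 to 87 in the others, and genes counted on 1 side only 74 and 57 to 88.

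The real split gave 1322 genes at an unadjusted p under 0.05, more than the 817 expected if no gene had changed, and the other splits 488 to 1056, so 1 of the 10 splits was as large. The share was 9.38% among genes of 10 CPM or more and 5.68% below. The excess depended on the tool. In DESeq2 689 of 22994 genes (3.00%) reached an unadjusted p under 0.05, below the share of 0.05 expected by chance. The quasi-likelihood test without a low-count filter gave 6.82% of 22994 genes. Thinning every library to the smallest total left 1300 genes at that level, which argues against the greater depth of the furosemide libraries as the source of the excess. Small treatment effects on many genes may account for it, as a hypothesis that these splits are too few to test. A batch shared by the libraries of a group stays open, since the labels give no dates.

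The 20 genes raised together in the control 2 library appear as lower after furosemide in the group comparison. Without that library their median log2 fold change was -0.11 with an SD of 0.16 over genes, where the choice of genes left room for about 0.88 in size, against a log2 ratio of 1.88 in control 2. The genes were chosen for standing at least 2-fold above each other library in control 2, so the other controls could not share the full rise. The fold change without control 2 therefore cannot decide whether the treatment was its source. The total count of control 2 was 0.994 of the mean of the other 5, which argues against depth. Of their 190 pairs, 27 lay within 0.1 of each other in log2 level, against a median of 6 and a maximum of 22 in 10000 random sets of 20 genes from the same range of levels. The random sets matched that range but not the distribution of levels within it. The excess of pairs therefore shows only that the levels of these genes cluster, not why. A candidate explanation for those shared levels is a family of near-identical copies whose reads were counted under many identifiers. No sequences were compared, and how reads matching several places were counted is not given in the sources used here. This candidate also leaves open why that pool held more of such transcripts. Tissue from a neighbouring region was not tested, for lack of symbols.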
